A study of Equus caballus with 4 samples.

How the data were processed

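Plasma and synovial fluid vesicles were collected by stepwise ultracentrifugation, synovial fluid after digestion with 10 µg/ml hyaluronidase, per the labels' protocols. RNA was pooled into 1 library per group from 6 horses, and the library preparation, ligating adapters to 5′ phosphates, targeted RNA of 18 to 30 nucleotides, per the labels. The submitters' processing notes name bcl2fastq, Trimmomatic 0.30 and DESeq2 1.16.1 without saying what each was used for. The aligner, the miRNA caller and the genome build are not given in the sources used here. The series text says that the second read file of the synovial control library is missing from the raw data.

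The authors deposited raw read counts of the mature arm at each listed precursor, 1 table of known and 1 of predicted miRNAs per library. They also deposited a series table of counts with 226 named and 1343 predicted miRNAs. The authors' tables of comparisons hold, per the file headers, counts, a column headed TPM, a log2 fold change, a p-value and an adjusted p-value. Division by the series table's column totals shows that the authors' column headed TPM is CPM of known plus predicted reads, not scaled by length. How the authors' p-values were computed is not given in the sources used here.

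A mature miRNA with several precursor rows in a library was counted once: rows whose mature sequences share 18 bases repeat the same reads, so the largest was taken, and rows without such overlap were added. A miRNA listed in only 1 of 2 libraries was not given a ratio, because the tables do not say whether it was absent or not reported. The series table was not used for the ratios, as it gives 0 for unlisted miRNAs and for some names, such as miR-199b-5p, it holds reads of the other arm. miRNA names with overlapping mature sequences, such as miR-103 and miR-107a, let-7a and let-7c, or miR-192 and miR-215, can share reads. Coordinates in the files count from 0, since end minus start equalled the precursor's length in 100% of the known rows, and were moved to count from 1. All columns of the series tables could be assigned to a library by name, with Normal read as control.

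CPM was computed from the deposited counts with the library's known miRNA reads as the total. Ratios carry an exact conditional (Clopper-Pearson) 95% interval from the 2 counts, and shares an exact binomial interval. A count of 0 was set to a floor of 3 counts, which is 1.46 CPM in the plasma control, 0.752 CPM in the plasma PTOA, 0.475 CPM in the synovial control and 0.538 CPM in the synovial PTOA library. No significance test between groups was run and no p-value computed, as there is 1 library per group.

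The design, the rules and 17 miRNA lists were fixed before the data were examined. Named miRNAs were, for PTOA over control, the 12 higher and 12 lower with the interval bound farthest from a ratio of 1, taking the bound nearest to 1. For synovial fluid over plasma they were 12 and 12 by the smaller such bound of the 2 pairs, and for both fluids up to 10 in each direction. The 5 most abundant miRNAs of each library and up to 4 members of each list were also named; miRNAs named beyond these were chosen after their values were seen. The lists were red blood cell, platelet, myeloid, lymphocyte, endothelial, liver, muscle, mesenchymal, chondrocyte, osteoarthritis literature, epithelial, neuronal, let-7, miR-17/92 clusters, miR-29, miR-30 and imprinted DLK1-DIO3. Some share members: 6 of the 12 listed osteoarthritis miRNAs and 3 of the 3 myeloid ones are in another list. A list of at least 3 measured miRNAs was set against 10000 random lists matched on deciles of mean log expression. Lists were matched to the names of known miRNAs, and predicted candidates were not assigned to any list.

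Alternatives were edgeR TMM factors and DESeq2 size factors from the 124 miRNAs listed in all libraries, totals without 10 abundant miRNAs or with predicted reads, minimums of 1 and 100 reads, limits of 1-fold and 4-fold, and thinning to 2060215 reads. Another 3 were chosen after seeing the data: at least 10 reads in both libraries, the series table with its zeros, and the sum over precursor rows. The ratio and interval code was tested on simulated counts drawn from the library sizes with known 4-fold differences. In the simulated plasma PTOA comparison of 141 miRNAs 95.0% of intervals held the true ratio, 54 of 55 changed miRNAs were called and 0 of 86 unchanged ones. The simulated counts held counting error alone around a shared profile and were scaled by the real totals. They check the code and give no rate of false calls for the real libraries.

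Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, were used. Reads outside the listed miRNAs, other RNA classes and target genes were not analysed here.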

Results

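Small RNA was sequenced from extracellular vesicles, membrane-bound particles that cells release into body fluids, of control horses and of horses in which post-traumatic osteoarthritis (PTOA, joint degeneration after an injury) had arisen naturally. Vesicles came from plasma and from synovial fluid, the fluid of the joint. Each of the 4 groups was 1 library made from a pool of 6 horses, so the groups have 1 library each, no comparison has a replicate check, and differences are described between libraries. Reads of known microRNAs (miRNAs, short RNAs that repress mRNAs) totalled 2060215 in the plasma control, 3988298 in the plasma PTOA, 6314700 in the synovial control and 5580329 in the synovial PTOA library. Levels are given as CPM, the count scaled to a common total of known miRNA reads. Intervals are exact 95% intervals from the read counts and cover counting error only, with each read taken as independent. Reads copied by PCR are not independent molecules, so the intervals can be too narrow. A miRNA is called higher or lower when at least 1 of the 2 libraries held 10 reads and the whole interval of the ratio lay beyond 2-fold.

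The plasma vesicle libraries were dominated by miR-486-5p, a miRNA abundant in red blood cells, which took 50.7% of known miRNA reads in the control library (interval 50.6% to 50.8%) and 33.7% in the PTOA library (33.7% to 33.7%). In synovial fluid miR-26a was the most abundant, with 27.0% of reads in the control (27.0% to 27.1%) and 17.5% in the PTOA library (17.5% to 17.6%). In the synovial control library miR-99a (14.9%), miR-125a-5p (9.91%), miR-148a (7.07%) and miR-21 (3.67%) followed, and in the synovial PTOA library miR-21 (12.3%), miR-125a-5p (8.91%), miR-148a (8.86%) and miR-99a (6.81%). After miR-486-5p, the plasma control library held miR-26a (8.31%), miR-21 (3.65%), miR-423-5p (3.05%) and let-7f (2.75%), and the plasma PTOA library miR-26a (9.20%), miR-122 (5.83%), let-7a (5.09%) and miR-21 (5.0%). The 10 most abundant miRNAs took 79.1% of the reads (79.0% to 79.1%) in the plasma control, 76.9% (76.8% to 76.9%) in the plasma PTOA, 74.4% (74.4% to 74.4%) in the synovial control and 66.9% (66.9% to 66.9%) in the synovial PTOA library. At least 10 reads were held by 136, 154, 152 and 139 known miRNAs in these libraries, in the same order, and at least 1 read by 164, 164, 157 and 160. In all, 229 known miRNAs were listed in at least 1 library and 124 in all 4.

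**Figure D1:**
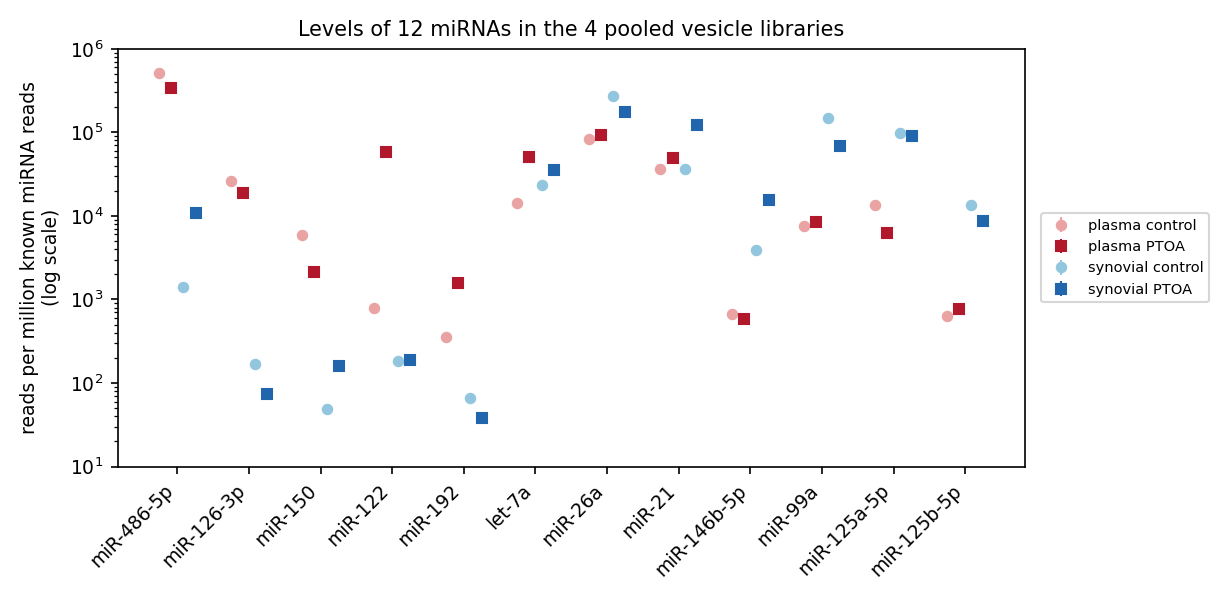
Level of 12 miRNAs (CPM of known miRNA reads, log axis) in the 4 pooled libraries; circles are control and squares PTOA libraries, plasma is red and synovial fluid blue, and the exact 95% counting intervals are smaller than most symbols. miR-122 stands at 797 CPM in the plasma control and 58328 CPM in the plasma PTOA library, and miR-486-5p at 1406 and 10895 CPM in the synovial control and PTOA libraries.

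The first comparison asked which vesicle miRNAs of plasma differed between the PTOA and the control library. The liver-abundant miR-122 had 1642 reads in the control and 232630 in the PTOA library and was 73.2-fold higher (69.7 to 76.9), and miR-192, also abundant in liver, was 4.39-fold higher (4.07 to 4.75). Of the let-7 family, regulators of cell differentiation, 4 of 7 members were higher: let-7a 3.54-fold (3.49 to 3.58), let-7c 5.16-fold (5.02 to 5.31), let-7e 2.95-fold (2.75 to 3.17) and miR-98 6.94-fold (6.30 to 7.67). The sequences of let-7a and let-7c overlap, so the same reads can count for both. The lymphocyte-abundant miR-150 was lower by 2.77-fold (2.70 to 2.85), with 12324 and 8610 reads, and miR-140-3p, from the cartilage-abundant miR-140 hairpin, by 2.37-fold, at 3870 CPM in the control and 1632 CPM in the PTOA library. Of 141 miRNAs compared, 36 were higher, 16 were lower and 89 were neither.

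Several of the largest plasma ratios rested on very few reads in the control library. There miR-329b had 1 read against 394 (ratio 204, interval 36.3 to 8059), miR-338-5p 2 against 307 (79.3, 21.8 to 658), miR-7177b 6 against 582 (50.1, 22.9 to 137) and miR-19a 4 against 324 (41.8, 16.2 to 154). The same held for miR-411 (1 against 124 reads, ratio 64.1, 11.3 to 2550), miR-18a (1 against 121, 62.5, 11 to 2489), miR-543 (1 against 104, 53.7, 9.43 to 2142), miR-132 (2 against 157, 40.6, 11 to 338) and the muscle miRNA miR-206 (3 against 176, 30.3, 10.2 to 148). With no read in the control library, miR-185 (181 reads) was at least 31.2-fold and miR-382 (62 reads) at least 10.7-fold higher against a floor of 3 counts, or 25.1-fold and 8.43-fold with the counting error of their own reads. Among the lower miRNAs, miR-149 had 297 reads in the control and 4 in the PTOA library (144-fold lower, 55.6 to 531), and miR-425 had 79 and 0 (at least 51-fold lower against the floor, or 40.5-fold with counting error). Further lower miRNAs were miR-211 (16.8-fold lower, 10.7 to 27.8), miR-885-5p (10.2-fold, 7.21 to 14.9), miR-129b-5p (5.29-fold, 4.18 to 6.74), miR-9055 (4.84-fold, 3.90 to 6.03), miR-9180 (3.95-fold, 2.97 to 5.30), miR-628a (3.38-fold, 2.76 to 4.16), miR-183 (3.23-fold, 2.64 to 3.98), miR-193a-5p (3.14-fold, 2.59 to 3.82) and miR-409-3p (2.74-fold, 2.33 to 3.22).

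By list, 4 of 7 members of the let-7 list were higher and none lower, with a median log2 ratio of 1.56, at the 99.6 percentile of 10000 random lists of the same size and expression. Of the 8 measured miRNAs of the imprinted DLK1-DIO3 cluster, 6 were higher and 1, miR-409-3p, was lower (median 4.02, percentile 98.5). Of the 6, miR-127 was 2.40-fold higher (2.01 to 2.89), and the other 5 (miR-329b, miR-370, miR-382, miR-411 and miR-543) had 0 or 1 read in the control library. With at least 10 reads in both libraries only miR-127 of this list was higher, at the main scaling alone or with predicted reads in the totals, and miR-409-3p was lower. Precursors of DLK1-DIO3 miRNAs such as miR-127, miR-329b, miR-411 and miR-543 lie near each other on chromosome 24, which the random lists do not allow for. miR-381 of this list had 65 reads in the control library, was not listed in the PTOA library and was not compared. Of the 5 liver-abundant miRNAs 2 were higher, and miR-885-5p was lower (median 1.53, percentile 93.5). miR-194 had a ratio of 2.89 (1.98 to 4.35) and miR-215 of 2.18 (1.68 to 2.87). Of the 4 red blood cell miRNAs measured none was called (median log2 ratio -0.48, percentile 1.41), and miR-486-5p had a ratio of 0.665. The fibroblast and smooth muscle (mesenchymal) list had 1 of 7 higher, miR-143 (3.24-fold, 3.09 to 3.40), the epithelial list 2 of 3, miR-200b (2.89-fold, 2.51 to 3.35) and miR-200a (6.05-fold, 4.57 to 8.17), and the muscle list 2 of 3, miR-206 and miR-499-5p (6.78-fold, 3.32 to 16.1). The muscle calls rested on 3 and 8 reads in the control library, and the list median was at percentile 53.1. The lymphocyte list had miR-181b higher (2.82-fold, 2.37 to 3.38) and miR-150 lower out of 4, the osteoarthritis literature list 2 higher (miR-132 and miR-98) and 1 lower (miR-140-3p) of 11, and the miR-17/92 cluster list 2 higher of 10 (miR-18a and miR-19a). No member was called in the platelet (4 members), myeloid (3), endothelial (3), miR-30 (4), miR-29 (2) and neuronal (2) lists. The only known miRNA compared from the chondrocyte list, miR-140-3p, was lower.

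List counts also depended on the scaling. With TMM factors 3 let-7 members, 5 DLK1-DIO3 members, 1 epithelial and 0 lymphocyte members were higher. The DLK1-DIO3 member lost was miR-127, which also lost its call with DESeq2 size factors and without the most abundant miRNAs in the totals, so the members left had 0 or 1 read in the control library. With TMM factors 2 red blood cell, 3 osteoarthritis literature and 2 miR-17/92 cluster miRNAs were lower, and so was 1 mesenchymal, 1 myeloid and 1 miR-30 member. With DESeq2 size factors the lower counts were 1 red blood cell, 2 osteoarthritis literature, 1 miR-17/92 cluster, 1 mesenchymal and 1 myeloid member. The epithelial miR-200b and the lymphocyte miR-181b lost their calls with DESeq2 size factors too. Without the most abundant miRNAs in the totals miR-146a was lower. With predicted reads in the totals 3 liver miRNAs were higher. The split of plasma calls depended on the scaling. With edgeR TMM factors 26 miRNAs were higher and 31 lower, and with DESeq2 size factors 29 and 24. With at least 10 reads required in both libraries, a limit set after the counts were seen, 20 were higher and 13 lower of 122, among them miR-122, miR-98 and let-7c.

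The second comparison asked the same of synovial fluid vesicles. miR-21, a miRNA raised in many inflamed and fibrotic tissues, was 3.35-fold higher in the PTOA library (3.33 to 3.36), with 231950 reads in the control and 685658 in the PTOA library, and miR-146b-5p, which dampens innate immune signalling, was 3.87-fold higher (3.82 to 3.93). The red blood cell miRNA miR-486-5p was 7.75-fold higher (7.58 to 7.92), with 8878 and 60796 reads, and miR-150 3.32-fold higher (2.91 to 3.79). In the other direction, miR-99a, the second most abundant miRNA of the control library, was 2.18-fold lower (2.17 to 2.19), and miR-126-3p, an endothelial miRNA, was 2.31-fold lower, at 169.9 CPM in the control and 73.7 CPM in the PTOA library. Of 137 miRNAs compared, 33 were higher, 21 lower and 83 neither.

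Further miRNAs higher in the PTOA synovial library were miR-1301 (10.5-fold, 8.08 to 13.8), miR-1296 (8.85-fold, 6.33 to 12.7), miR-450c (6.82-fold, 5.42 to 8.65), miR-450a (6.47-fold, 5.13 to 8.25), miR-135a (6.24-fold, 4.24 to 9.47), miR-132 (5.20-fold, 4.02 to 6.81), miR-1468 (4.70-fold, 4.0 to 5.54) and miR-1379 (4.59-fold, 4.27 to 4.94). The mature sequences of miR-450a and miR-450c overlap, so the same reads can count for both. miR-185 had 1 read in the control and 344 in the PTOA library (ratio 389, 69.4 to 15419.5), and miR-363 had 5 and 285 (64.5, 27.3 to 200). Most of the lower miRNAs had 10 reads or fewer in the PTOA library. Among them were miR-19a (339 and 1 reads, 300-fold lower, 53.4 to 11867), miR-34a (209 and 2, 92.3-fold, 25.2 to 768), miR-127 (203 and 2, 89.7-fold, 24.5 to 746), miR-29b (350 and 10, 30.9-fold, 16.6 to 65.1), miR-219-3p (105 and 1, 92.8-fold, 16.3 to 3699), miR-411 (104 and 1, 91.9-fold, 16.1 to 3665), miR-409-3p (74 and 2, 32.7-fold, 8.74 to 275) and miR-628a (126 and 0, at least 37.1-fold against the floor, or 29.7-fold with counting error). miR-499-5p had 700 and 44 reads and was 14.1-fold lower (10.4 to 19.5).

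Among the lists, 3 of 4 red blood cell miRNAs were higher in the PTOA synovial library, miR-486-5p, miR-363 and miR-92a (2.22-fold, 2.18 to 2.25), while miR-16 had a ratio of 0.492 (0.449 to 0.538). The list median was 2.05 on the log2 scale, at percentile 99.7, and with TMM factors, DESeq2 size factors or totals without the most abundant miRNAs 2 members were higher and 1 was lower. The 3 measured epithelial miRNAs of the miR-200 family were lower: miR-200c (293 and 1 reads, 259-fold lower, 46.1 to 10262), miR-200a (166 and 1, 147-fold, 26.0 to 5829) and miR-200b (226 and 3, 66.6-fold, 22.5 to 325). The mesenchymal list had 2 of 6 lower and none higher, with a median log2 ratio of -0.81, at percentile 0.01. Under the same 3 scalings 3 members were lower. Members listed in only 1 of the 2 synovial libraries were not compared, among them miR-214 (1415 reads in the control) and the miR-199 arms. miR-199a-5p had 30076 reads in the control and miR-199a-3p 101373 in the PTOA library, so the list values leave out abundant members. Besides miR-99a, miR-10a was lower (3.02-fold, 2.90 to 3.15). At the main scaling miR-100 (ratio 0.515), miR-125b-5p (0.631), miR-10b (0.881) and miR-143 (0.971) were not called. Precursors of miR-99a and miR-125b-5p lie close together on chromosome 26, and those of miR-100 and miR-125b-5p on chromosome 7. The random lists do not allow for such neighbours. The 3 measured DLK1-DIO3 miRNAs, miR-127, miR-411 and miR-409-3p, were lower (median -6.49, percentile 12.9). The osteoarthritis literature list had 4 higher (miR-21, miR-146b-5p, miR-132 and miR-9a) and 1 lower (miR-34a) of 11, and the let-7 list none of 7 in either direction. In the lymphocyte list 1 of 5 was higher (miR-150), in the endothelial list 1 of 3 lower (miR-126-3p), in the liver list 1 of 3 lower (miR-215, 44 and 1 reads), and in the miR-17/92 cluster list 2 of 9 higher and 1 lower, or 1 higher under the 3 scalings named for the red blood cell list. One member each was lower in the muscle list (miR-499-5p, of 2) and the miR-29 list (miR-29b, of 2), 1 of 2 was higher in the neuronal list (miR-9a), and none was called in the platelet (3), myeloid (2), miR-30 (4) and chondrocyte (1) lists. miR-140-3p had a ratio of 1.5.

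Here too the split moved with the scaling, to 25 higher and 27 lower with TMM factors, 27 and 26 with DESeq2 size factors and 26 and 26 when the most abundant miRNAs were left out of the totals. With at least 10 reads in both libraries, 31 were higher and 7 lower of 121, and the miR-200 family and DLK1-DIO3 miRNAs were no longer compared.

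Setting the fluids side by side, 118 miRNAs were compared in both. Higher in PTOA in both fluids were miR-185, miR-132, miR-1301 (3.12-fold in plasma, 2.58 to 3.81), miR-744 (2.37-fold in plasma, 2.22 to 2.54, and 3.93-fold in synovial fluid, 3.81 to 4.05), miR-1307 (2.74-fold, 2.59 to 2.90, and 2.29-fold, 2.21 to 2.39) and miR-1271a (2.81-fold, 2.49 to 3.18, and 2.13-fold, 2.02 to 2.25). These 6 compare with 6.88 for independent lists of the same lengths. Lower in both were miR-628a, miR-183 (29 and 3 reads in synovial fluid, 8.54-fold lower, 2.65 to 43.8) and miR-409-3p, 3 where independent lists give 1.58. Higher in plasma and lower in synovial fluid were 7 (4.03 for independent lists), and lower in plasma and higher in synovial fluid were 2, miR-149 and miR-150 (2.70 for independent lists). Across miRNAs, which are not independent replicates, the log2 ratios of the 2 fluids had a Pearson correlation of -0.10 and a Spearman correlation of -0.00070. With TMM factors 2 miRNAs were higher in both fluids and 5 lower in both, and with DESeq2 size factors 3 were higher in both.

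**Figure D2:**
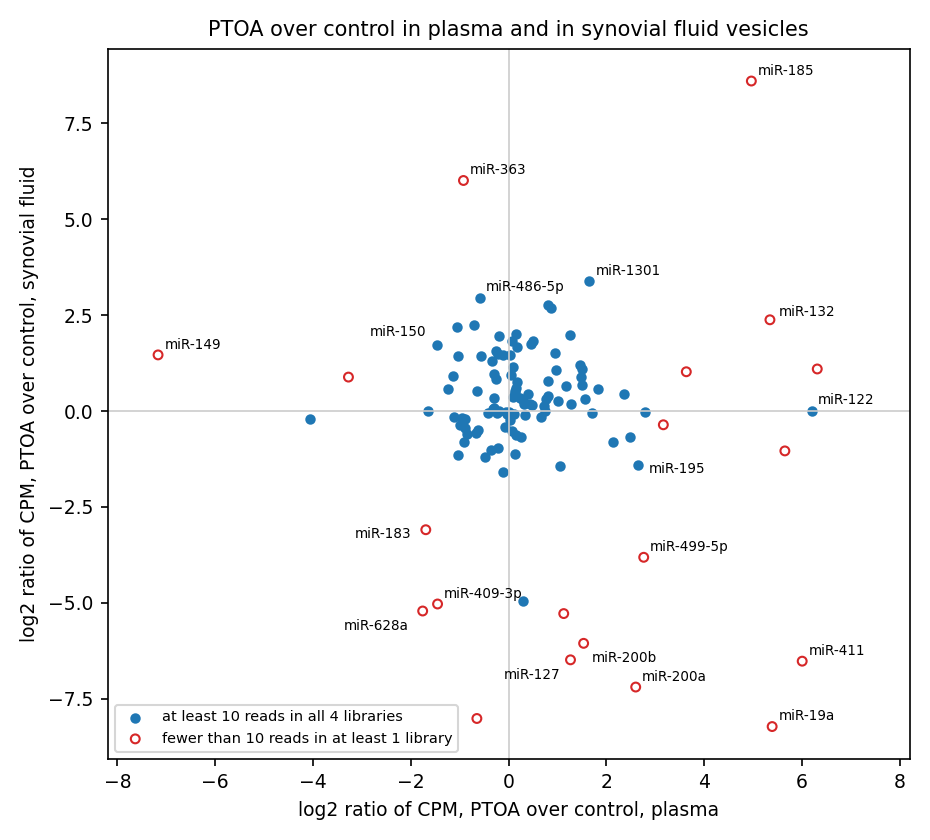
Log2 ratio of CPM, PTOA over control, of each of 118 miRNAs in plasma (horizontal axis) and synovial fluid (vertical axis); filled points had at least 10 reads in all 4 libraries and the 20 open points fewer in at least 1. Most points far from 0 on both axes are open, while miR-122 and miR-486-5p are filled and far from 0 in 1 fluid.

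The third question was how synovial fluid vesicles differ from plasma vesicles, asked separately in control and PTOA libraries. Hyaluronidase was used on synovial fluid alone, and whether both fluids came from the same horses is not given in the sources used here. Several, but not all, miRNAs of the mesenchymal list were higher in synovial fluid. miR-99a was 19.4-fold higher in the control pair (19.1 to 19.7) and 8.16-fold in the PTOA pair (8.07 to 8.25). miR-125b-5p was 21.3-fold (20.1 to 22.5) and 11.2-fold (10.8 to 11.6) higher, and miR-100 7.75-fold (7.52 to 7.99) and 4.64-fold (4.52 to 4.75). From the same list, miR-10a was lower in both pairs. miR-143 was not called in the control pair (ratio 0.689) and was 4.84-fold lower in the PTOA pair (4.67 to 5.03). miR-125a-5p was 7.36-fold (7.27 to 7.45) and 14.4-fold (14.2 to 14.6) higher and miR-146b-5p 5.97-fold (5.65 to 6.31) and 26.5-fold (25.5 to 27.7). Lower in synovial fluid were the red blood cell miRNA miR-486-5p, 361-fold (353 to 368) and 30.9-fold (30.7 to 31.2), miR-126-3p 153-fold (144 to 163) and 253-fold (229 to 279), and miR-150 124-fold (111 to 139) and 13.5-fold (12.6 to 14.4). In the control pair 45 miRNAs were higher and 41 lower in synovial fluid of 135, and in the PTOA pair 41 and 40 of 130. With the most abundant miRNAs left out of the totals, the PTOA pair had 30 higher and 54 lower, and with TMM factors 48 higher and 35 lower.

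In both conditions 27 miRNAs were higher in synovial fluid, against 13.0 for independent lists, 23 were lower, against 10.2, and 3 went opposite ways, miR-19a, miR-411 and miR-499-5p. Also among the 12 higher were miR-211 (11.9-fold, 10.3 to 13.9, and 172-fold, 112 to 278), miR-671-3p (55.8-fold, 27.0 to 139, and 9.16-fold, 7.83 to 10.8), miR-1180 (67.1-fold, 35.3 to 147, and 5.85-fold, 4.95 to 6.95) and miR-224 (26.8-fold, 14.5 to 56.1, and 479-fold, 132 to 3958). In the plasma control library miR-671-3p had 7, miR-1180 9 and miR-224 10 reads, and miR-224 had 2 in the plasma PTOA library. The rest of the 12, miR-362-5p, miR-497 and miR-331, had at most 5 reads in each plasma library and between 200 and 1140 in each synovial library. Also among the 12 lower were miR-363 (1404-fold, 601 to 4329, and 11.5-fold, 10.1 to 13.0), miR-16 (6.01-fold, 5.65 to 6.39, and 9.48-fold, 8.75 to 10.3), miR-328 (6.56-fold, 6.29 to 6.84, and 9.31-fold, 9.02 to 9.61), miR-10a (5.71-fold, 5.58 to 5.85, and 16-fold, 15.4 to 16.6), miR-504 (14.2-fold, 11.9 to 17, and 9.64-fold, 8.66 to 10.7), miR-139-5p (6.01-fold, 5.46 to 6.62, and 9.01-fold, 8.10 to 10.1), miR-183, miR-409-3p and miR-628a. The 1404-fold value of miR-363 rests on 5 reads in the synovial control library. With at least 10 reads in both libraries, 30 miRNAs were higher and 40 lower of 119 in the control pair, and 35 and 27 of 111 in the PTOA pair. The log2 ratios of the 2 pairs had a Pearson correlation of 0.54 across 120 miRNAs, with a Spearman correlation of 0.68.

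The mesenchymal list had 5 of 7 higher and 1 lower (miR-10a) in the control pair (median log2 ratio 2.95, percentile 99.9). In the PTOA pair 4 of 6 were higher and 2, miR-10a and miR-143, were lower (2.24, percentile 99.3). The red blood cell list had 4 of 4 lower in the control pair (median -5.54, percentile 0.16) and 4 of 5, or 5 of 5 without the most abundant miRNAs in the totals, in the PTOA pair (-3.52, percentile 0.80), and the liver list 3 of 4 (-2.20, percentile 0.98) and 3 of 3 (-8.29, percentile 0.54). miR-122 was 4.30-fold lower in synovial fluid in the control pair (3.99 to 4.64) and 312-fold lower in the PTOA pair (294 to 332). In the endothelial list miR-221 and miR-222 were higher and miR-126-3p lower in both pairs, and in the platelet list miR-24 was higher and miR-191a and miR-197 lower in both. The miR-17/92 cluster list had 6 of 9 lower and 1 higher, then 6 of 10 lower. The lymphocyte list had 1 higher and 3 lower of 5, then 1 and 1 of 4. The osteoarthritis literature list had 2 higher and 1 lower of 10, then 4 and 1 of 10, and the let-7 list 2 higher and 0 lower of 7, then 1 and 2 of 7. For the epithelial list 1 of 3 was lower, then 3 of 3, and for the DLK1-DIO3 list 1 was higher and 1 lower of 4, then 4 of 4 were lower. In the myeloid list 1 of 2 was lower in the control pair (miR-155) and none in the PTOA pair. miR-140-3p, the only known miRNA compared from the chondrocyte list, had a ratio of 1.21 (1.18 to 1.24) in the control pair. It was 4.31-fold higher in the PTOA pair (4.19 to 4.42). miR-30d was the 1 of 4 miR-30 members that was higher in both pairs, and in the miR-29 list miR-29a was higher in both pairs, miR-29c lower in the control pair and miR-29b lower in the PTOA pair. In the muscle list miR-499-5p was higher in the control pair and lower in the PTOA pair, and no neuronal miRNA was called. Under other scalings these list counts moved by at most 2 members in a direction. Without the most abundant miRNAs in the totals, the neuronal miR-9a was lower in the control pair and the neuronal miR-128 in the PTOA pair. In the PTOA pair the myeloid miR-146a was higher with TMM factors, and the myeloid miR-155 was lower without the most abundant miRNAs. There miR-499-5p lost its call with TMM factors. miR-30d lost its call in the PTOA pair with DESeq2 size factors, without the most abundant miRNAs and with predicted reads in the totals.

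Besides known miRNAs, the deposited files list predicted miRNA candidates for each library, 321 in the plasma control, 390 in the plasma PTOA, 368 in the synovial control and 502 in the synovial PTOA library, with 204602, 301356, 866998 and 732390 reads. They made up 9.03%, 7.03%, 12.1% and 11.6% of all miRNA reads. Between any 2 libraries 42 to 57 mature sequences were identical, and 1171 of the distinct sequences were listed in 1 library alone against 24 in all 4. Candidates with the same sequence can repeat the same reads, so these read sums count some reads more than once.

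The authors' deposited table for plasma calls 658 miRNAs, 377 higher and 281 lower in PTOA, and the authors' deposited table for synovial fluid 805, 464 higher and 341 lower. In the authors' deposited tables, 591 and 731 of these are predicted candidates, and 570 and 700 of the candidates are listed with 0 reads in 1 of the 2 libraries. For the named miRNAs that could be compared here, 46 in plasma and 45 in synovial fluid, the log2 fold change in the authors' deposited tables minus the log2 CPM ratio had a median of -0.03 and -0.43. In the authors' deposited table miR-122 has a log2 fold change of 6.16 in plasma and miR-21 of 1.31 in synovial fluid, and miR-146b-5p of 1.52. A further 21 and 29 named miRNAs in the authors' deposited tables were not listed in both libraries and were given no ratio here. Since each group is 1 pooled library, the p-values in the authors' deposited tables rest on no replicate and are not repeated.

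In the files' coordinates, counted from 1, the miR-122 precursor lies on chromosome 8 from 79152587 to 79152643, miR-21 on chromosome 11 from 34161384 to 34161443, miR-363 on chromosome X from 110758369 to 110758433 and miR-99a on chromosome 26 from 16008731 to 16008789. The miR-486-5p precursors overlap on both strands of chromosome 27, between 3721450 and 3721551. The genome build of these coordinates is not given in the sources used here, and no gene annotation was used with them.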

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

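The tests of explanations in this part were chosen after the result was seen. The 9 miRNAs called in opposite directions by PTOA over control in plasma and synovial fluid are given as the synovial minus the plasma log2 ratio, and the difference was not tested, since each group is 1 library. The values are -13.61 for miR-19a, -12.52 for miR-411, -9.79 for miR-200a, -7.75 for miR-127, -7.59 for miR-200b, -6.57 for miR-499-5p, -4.06 for miR-195, 3.20 for miR-150 and 8.63 for miR-149. With at least 10 reads required in both libraries of each pair, 2 opposite calls were left, miR-150 (12324 and 8610 reads in plasma, 305 and 895 in synovial fluid) and miR-195 (11 and 134, then 1242 and 414).

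Large ratios that rest on at most 10 reads in 1 library made 19 of the plasma and 17 of the synovial PTOA calls. After thinning every library to the smallest total 91.7% of these calls were still made, so most did not need the reads beyond that total. Most had many more reads in the other library, which thinning could hardly undo. The test therefore does not decide whether library depth was their source. The plasma control library is the smallest and was itself not thinned. Thinning therefore cannot tell whether the low counts of that library are reliable. Few starting molecules copied many times may leave a gap in the counts: 3 of the 4 libraries had fewer known miRNAs at 11 to 50 reads (7, 6, 10 and 5) than at 1 to 10 (29, 10, 5 and 23) and at 51 to 250 (33, 38, 34 and 19), but the synovial control did not. This explanation stays open, because the rule by which the tables list a miRNA also shapes its low counts. A difference between PTOA and control horses stays open too and was not tested.

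miR-486-5p and miR-363 were higher in the PTOA than in the control synovial library. Plasma vesicles carried into the PTOA synovial pool could add miR-486-5p, and its excess needs a plasma share of 1.87% with the plasma control or 2.82% with the plasma PTOA library as the source. At that share miR-126-3p would stand at 487 or 524 CPM, while its whole level was 73.7 CPM (upper bound 81.1). From the PTOA source miR-122 would stand at 1642 CPM, while it was 187 CPM. The shares were set from miR-486-5p alone. miR-363 stood at 1112 and 586 CPM in the plasma control and PTOA libraries, and at 0.792 and 51.1 CPM in the synovial ones. At either share its plasma level would give only a part of that synovial rise. With the plasma control as the source, miR-126-3p was the 1 of 20 plasma-abundant miRNAs below the needed level; most others are abundant in synovial fluid itself, so this explanation is not excluded for a part of the excess. Red blood cell material may also contribute, but of the 2 other measured members 1, miR-92a, was higher and miR-16 was not, while miR-144 had 135 reads in the PTOA and was not listed in the control synovial library, and no red blood cell library was used here to decide; a change within the PTOA joint stays open as well.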

How the results depend on the processing

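At least 10 reads in both libraries, the series table with its zeros and the sum over precursor rows were chosen after seeing the data. Counts are given as higher and lower for plasma PTOA (main 36 and 16), synovial PTOA (33 and 21), the control fluids (45 and 41) and the PTOA fluids (41 and 40), then as higher in both, lower in both and opposite for PTOA in both fluids (6, 3 and 9) and for the fluids in both conditions (27, 23 and 3), and the causes of the moves were not tested unless the setting makes them. Counts within 1.5 times of the main one are left out. A limit of 1-fold gave 74 and 52, 71 and 53, and 64 and 62 for the PTOA fluids, then 37, 23 and 39, and 50, 45 and 14; fewer or more miRNAs pass by construction. At 4-fold it was 22 and 5 in plasma, 11 higher in synovial fluid, 28 higher in the control fluids, 21 higher in the PTOA fluids, then 2, 0 and 3, and 12 and 14. TMM factors gave 31 lower in plasma, and 2 higher and 5 lower in both fluids; DESeq2 size factors gave 3 higher in both. Leaving out the most abundant miRNAs gave 35 lower in both conditions, and a minimum of 100 reads 1 lower in both fluids. At least 10 reads in both libraries gave 20 higher in plasma, 7 lower in synovial fluid, 0 lower in both, and 2 and 0 opposite. The series table with its zeros gave 25 lower in plasma, 34 lower in synovial fluid, 67 lower in the PTOA fluids, 7 lower in both fluids, and 35 lower in both conditions with 6 opposite. No read minimum, the sum over precursor rows and thinning left all counts within 1.5 times. TMM moved every log2 ratio by -0.51 in plasma, -0.28 in synovial fluid and 0.27 for the PTOA fluids, and DESeq2 by -0.35, -0.23 and -0.07, with -0.18 for the control fluids. Totals without the most abundant miRNAs moved the ratios by -0.25 in synovial fluid, -0.30 for the control fluids and -0.48 for the PTOA fluids. With predicted reads in the total the 10 most abundant miRNAs took 71.9%, 71.5%, 65.4% and 59.1%. Shared seeds of predicted miRNAs numbered 72 for the plasma libraries, 77 for plasma PTOA and synovial control and 94 for the synovial libraries, where 44, 45 and 57 mature sequences were identical. Known miRNA reads ranged from 2060215 to 6314700 per library, and the ratios of miRNAs with few reads have wide counting intervals. No paired analysis was possible because each group is 1 pooled library.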

Other observations

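The test in this part and the miRNAs and candidates named in it were chosen after the values were seen. Among the predicted candidates listed in all 4 libraries, ugagguaguaguuugugcuguu, has the sequence known as let-7i in other mammals, from general knowledge and not checked against a database here. It had 27467 reads in the plasma control, 96236 in the plasma PTOA, 254869 in the synovial control and 319210 in the synovial PTOA library, and was 3.03-fold (2.99 to 3.07) and 2.37-fold (2.35 to 2.39) higher in synovial fluid than in plasma. Its PTOA over control ratios were 1.81 (1.79 to 1.83) in plasma and 1.42 (1.41 to 1.42) in synovial fluid. Likewise ucagugcaugacagaacuuggg, known as miR-152, was 15.1-fold (14.3 to 15.9) and 33.2-fold (31.5 to 34.9) higher in synovial fluid, and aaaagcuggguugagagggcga, known as miR-320a, 3.83-fold (3.75 to 3.92) and 2.85-fold (2.80 to 2.90). The candidate uaugugccuuuggacuacaucgu was higher in PTOA in plasma (35 and 257 reads, 3.79-fold, 2.66 to 5.57) and in synovial fluid (1737 and 10468 reads, 6.82-fold, 6.48 to 7.18). The sequence uguaaacacccgacuggaagcc had a PTOA over control ratio of 0.404 (0.400 to 0.409) in synovial fluid and of 0.723 (0.700 to 0.747) in plasma.

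Some miRNAs were listed in 1 fluid or condition alone and were given no ratio against the libraries that did not list them. miR-223, abundant in neutrophils, had 311 and 849 reads in the plasma control and PTOA libraries and was not listed in either synovial library. miR-144, abundant in red blood cells, had 2095 reads in the plasma PTOA and 135 in the synovial PTOA library and was not listed in either control library. For miR-199b the listed arm differed between libraries: 5p reads numbered 55990 in the synovial control and 3p reads 101322 in the synovial PTOA library, and the series table holds both numbers under miR-199b-5p. For miR-199a the listed arm differed in the same way, with 30076 5p reads and 101373 3p reads. The 3p sequences of miR-199a and miR-199b overlap, so the same reads can count for both.

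Predicted miRNAs above 0 in only 1 library among the authors' calls could reflect that each library's candidates were predicted on their own. At 1000 reads or more, 42.6% (29.2% to 56.8%) of the synovial control candidates had their locus listed in the synovial PTOA library and 58.8% (44.2% to 72.4%) the other way, against 95% (87.7% to 98.6%) and 97.4% (90.9% to 99.7%) of known miRNAs. In plasma the shares were 60.0% (42.1% to 76.1%) and 71.9% (53.3% to 86.3%), against 100% (94.0% to 100%) and 93.6% (85.7% to 97.9%). The candidates' interval lay below that of known miRNAs in 3 of the 4 directions, with the plasma PTOA candidates as the exception. The share alone does not separate per-library prediction from candidates present in 1 library, because reads at an unlisted locus are not given.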
